A study of Mus musculus with 19 samples.

How the data were processed

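Total RNA (100 ng per array, RNA integrity number above 9, per the labels) from differentiated 3T3-L1 cells was hybridised to whole-transcript mouse arrays of Affymetrix (Mouse Gene, version 1.1), 4 arrays per group for control, PA, PMA and SA and 3 for OA. The deposited values are log2 RMA expression per probe set, normalised between arrays by the authors with RMA in R 2.15.0 and affy 1.34.0. The table held 35556 probe sets for 19 arrays, with values from 1.97 to 13.3. The original scan files were not used here, so background correction and summarisation were taken as deposited.

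Of the probe sets 23099 were listed in the gene annotation of the array, 21218 with 1 gene symbol and 1881 with several; 12457 were not named. For each of 18820 gene symbols the probe set with the highest mean over all arrays was used, with no filter on low values, and 1386 genes had more than 1 probe set. Gene identifiers were checked against the annotation of GRCm38.p6, where 21185 were found, 33 were not and 0 symbols differed. Probe sets with no symbol or several were tested apart.

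A linear model with 1 mean per group was fitted to all 19 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), so that the 5 groups shared 1 estimate of the spread. From it came 11 contrasts: each acid against control, the saturated against the monounsaturated acids, PA against PMA, SA against OA, PA against SA, PMA against OA, the interaction of chain length and double bond, and the mean of the 4 acids against control. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene passed at an adjusted p under 0.05. Errors are standard errors from the model unless said otherwise, and intervals are 95% intervals.

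For the shifts of gene lists, 30 lists of pathways, stress responses and cell type markers were written down with 770 entries, of which 700 were measured. Each was tested in each contrast with camera at a preset correlation of 0.01, adjusted over the lists of the contrast, with camera at an estimated correlation and with fry. Camera asks whether the members rank higher or lower than the other genes. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. Genes were named by a rule: the 6 largest rises and 6 largest falls among genes past the threshold whose groups did not overlap, up to 4 members with the smallest p of a list described, and a panel of 25 genes of lipid metabolism, adipocyte function and stress, 23 of them measured. The contrasts, tests, lists, rule for named genes and most alternatives were chosen before the data were examined.

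Responses of the acids were compared by Pearson correlation across genes and by shared calls, beside values simulated with unchanged groups against the same controls and values with the 4 controls split into 2 and 2, averaged over the 6 ways to do so. The fit was tested on simulated data with 200 changed genes in each of 5 simulations per acid. Errors were drawn independently, with the same spread of a gene in every group. Genes changed by 0.3 were recovered in 49.6% (OA) to 62.4% (SA), genes changed by 0.5 in 93.4% to 94.9% and all of those changed by 1, and 4.04% to 5.53% of the calls were false. A list shifted by -0.15 passed in 5 of 5 simulations for each acid.

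Alternatives tried were leaving out the dimmest genes (the lowest 1 in 3 by mean), every probe set without collapsing to genes, the average of a gene's probe sets, cyclic loess between arrays on the deposited values, a trended robust spread, the replicate number as a block, only the arrays of the groups compared, each array left out in turn, and the estimated correlation for lists. Array quality weights, leaving out PA replicates 2 and 4, leaving out PMA replicates 1 and 4, cyclic loess with PA replicate 1 left out, and the inflammatory list in SA against OA with only those arrays were added after seeing the data. Chance was weighed by other splits of the arrays compared, all 35 where 7 or 8 arrays entered and 100 drawn at random where more did.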

Results

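Gene expression was measured on 19 microarrays of differentiated 3T3-L1 cells, a mouse fibroblast line that is turned into fat-storing adipocytes in culture. The cells stood without serum from day 7 of differentiation and were given 1 fatty acid at 250 µM for 48 h from day 8. Palmitic acid (PA, n = 4) has 16 carbons and no double bond, palmitoleic acid (PMA, n = 4) 16 carbons and 1 double bond, stearic acid (SA, n = 4) 18 carbons and no double bond, and oleic acid (OA, n = 3) 18 carbons and 1 double bond. Control cells (n = 4) received ethanol and 2% albumin, the solvent and carrier of the acids. The labels call the arrays of a group biological replicates. The p-values of single genes rest on the spread between them, shared over the 5 groups. Camera p-values at the preset correlation compare list members with the other genes. They do not estimate from the arrays how the members vary together. The comparisons ask which genes each acid changed, and whether acids that differ by the double bond or by 2 carbons changed different genes.

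Values are log2 RMA expression, and differences are log2 fold changes ± SE. The genes named most often were measured by probe sets 10454782 (Egr1), 10481627 (Lcn2), 10349947 (Fmod), 10389207 (Ccl5), 10498024 (Slc7a11), 10455970 (BC023105) and 10478847 (Znfx1). Array medians over the whole chip lay between 5.23 and 5.43, and pairs of arrays correlated at 0.992 to 0.999. The first principal component held 31.2% of the variance, and PA replicates 2 and 4 stood lowest on it, at -27.4 and -13.8. The second component held 13.7%, and PMA replicates 1 and 4 stood highest on it, at 17.1 and 11.9. Those 2 PMA arrays had higher medians (5.41 and 5.35) than the other two (5.24 and 5.27), and PA replicate 2 had the smallest interquartile range, 3.25. The labels give no batch or date, so no within-batch value could be computed, and the number of arrays limits the precision.

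**Figure D1:**
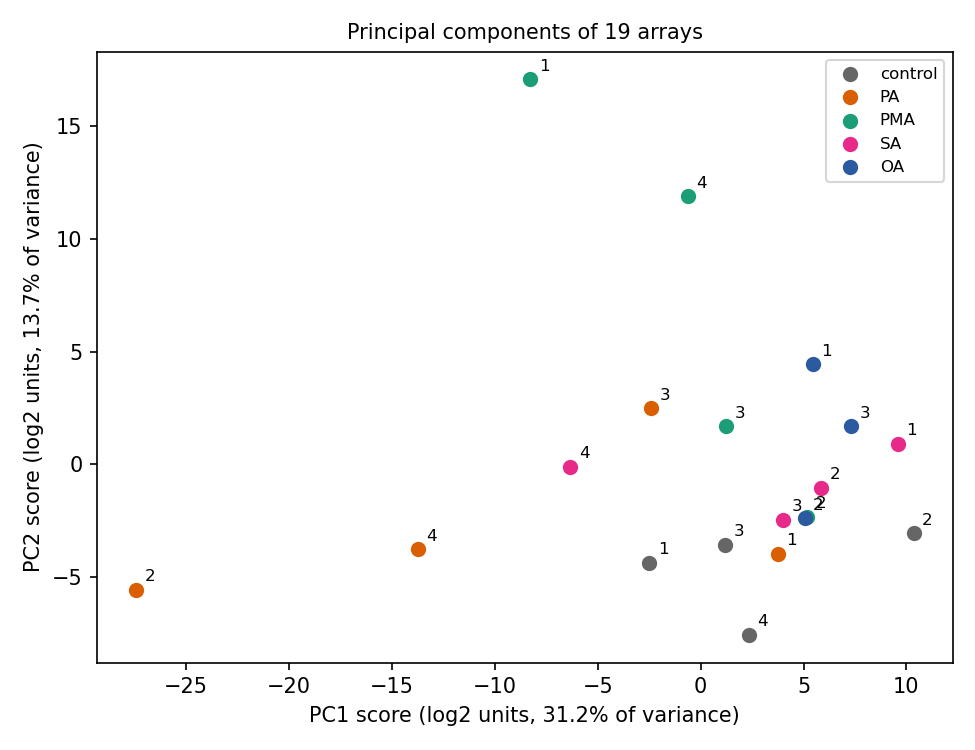
Scores of the 19 arrays on the first principal component (31.2% of the variance) and the second (13.7%), in log2 units, coloured by group and numbered by replicate. PA replicate 2 lies lowest on the first component, at -27.4, and PMA replicate 1 highest on the second, at 17.1.

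PA changed no gene past the threshold. The closest was Ccl5, a chemokine that draws in T cells and macrophages, at 6.71 with PA against 5.93 in control cells, a difference of 0.77 with adjusted p = 0.094; it is named here after its value was seen. Genes of lipid handling did not pass: the log2 difference was -0.06 ± 0.05 for Plin2, which coats lipid droplets, -0.11 ± 0.06 for Cd36, the fatty acid transporter, -0.05 ± 0.05 for Fabp4, the adipocyte fatty acid binding protein, -0.01 ± 0.05 for Scd1, the enzyme that puts the double bond into PA and SA, and -0.10 ± 0.08 for Pdk4, which spares glucose by inhibiting pyruvate dehydrogenase. Their adjusted p ran from 0.337 for Cd36 to 0.959 for Scd1, and the 95% interval for Scd1 reached from -0.10 to 0.09. Stress and inflammation genes of the panel did not pass either: 0.01 for Hspa5, a chaperone of the endoplasmic reticulum, -0.24 for Il6 and 0.17 for Ccl2, both secreted inflammatory signals.

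None of the 30 gene lists passed with PA, and the smallest camera adjusted p was 0.217, for the desaturases and elongases (median -0.03). With limma 0 genes passed although 2900 had an unadjusted p under 0.05, and 2 passed with a trended, robust spread. In simulated data 61.5% of genes changed by 0.3 and 94.9% of those changed by 0.5 were recovered in this comparison. The simulation gave every group the same spread, with independent errors. The PA arrays lay farther from their group mean (SD 0.116, against 0.0777 to 0.0838 in the other groups). These shares may thus not hold for PA. The count rested on single arrays: without PA replicate 1 it was 510 (397 higher and 113 lower), and without PA replicate 2 it was 1. The 397 genes were 0.03 higher than control on average in PA replicate 1, against 0.44, 0.25 and 0.35 in replicates 2, 3 and 4. They were called without replicate 1, so part of this gap comes from the choice of genes.

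PMA raised 36 genes and lowered 14. The largest rise was of BC023105, an uncharacterised transcript (0.64 ± 0.09, adjusted p = 0.00124), from 5.03 in control cells to 5.68. Fmod, a collagen-binding proteoglycan of the extracellular matrix, rose by 0.55 ± 0.08 (adjusted p = 0.0033), and Cpe, which trims peptide hormones, by 0.41 ± 0.06 (adjusted p = 0.00461). Among the falls were Egr1, a transcription factor induced within minutes of growth signals (-0.57 ± 0.07, adjusted p = 0.000502), Ccl7, a monocyte chemokine (-0.47 ± 0.06, adjusted p = 0.00124), and Rpa3, a subunit of the single-strand DNA binding protein RPA (-0.55 ± 0.08, adjusted p = 0.00508). Each of these 6 genes passed whichever array was left out. A dimmer probe set of Rpa3, 10353032, went the same way by less (-0.16).

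The other large changes with PMA were close to the threshold, apart from that of Znfx1. The calls of Sfrp2, Phex, Plagl1 and Ankrd37 each ended when any of 12, 14, 13 and 15 of the 19 arrays in turn was left out, and that of Sap30 with any of 2. Sfrp2, a secreted modulator of Wnt signals, rose by 0.50, Phex, a membrane peptidase of bone, by 0.39, and Plagl1, a zinc finger transcription factor, by 0.39, each with adjusted p = 0.0444, which became 0.172 without control replicate 4. Sap30, a subunit of a histone deacetylase complex, fell by 0.49 (adjusted p = 0.0189, and 0.113 without control replicate 4), and Ankrd37 fell by 0.45 (adjusted p = 0.0444, and 0.165 without control replicate 4). Znfx1, a helicase that senses viral RNA, fell by 0.57 (adjusted p = 0.000811) on its brighter probe set, while its dimmer probe set 10489850 went the other way (0.09). The Znfx1 call held whichever array was left out. The median absolute change of the 50 genes was 0.30, and 1 of them exceeded 1.5-fold.

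By camera the matrix and fibroblast lists ranked above the other genes with PMA, and the inflammatory, immediate early, ribosomal and oxidative phosphorylation lists below them, none of which passed with an estimated correlation. Of 36 measured extracellular matrix genes, 2 rose, 0 fell and 34 did not pass, the 2 being Col1a1 and Col6a1, collagen chains (0.26 and 0.20, both adjusted p = 0.0463). With p adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 0.0344, but adjusted p = 0.903 with an estimated correlation). Of 22 preadipocyte and fibroblast markers, 1 rose (Col1a1), 0 fell and 21 did not pass, and Dlk1, the preadipocyte marker lost in differentiation, was 0.26 higher (adjusted p = 0.0611). Adjusted over the list alone 6 rose and 0 fell (camera adjusted p = 0.0119, adjusted p = 0.903 with an estimated correlation). Among 32 inflammatory cytokines, chemokines and acute phase genes 0 rose, 1 fell (Ccl7) and 31 did not pass, with Cxcl12, a chemokine of stromal cells, 0.21 higher (adjusted p = 0.0606). With p adjusted over the list alone 2 rose and 6 fell (median -0.01, camera adjusted p = 1.12e-05, adjusted p = 0.113 with an estimated correlation). The calls of Col1a1 and Col6a1 ended when control replicate 4 was left out (adjusted p = 0.172 and 0.165).

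Of 18 immediate early genes, which answer growth signals within an hour, 0 rose with PMA, 1 fell (Egr1) and 17 did not pass; Jun was 0.17 higher and Fos -0.27 different (adjusted p = 0.0985 and 0.15). Adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 1.91e-06, adjusted p = 0.201 with an estimated correlation). None of 39 ribosomal protein genes passed by itself, with Rps24 at -0.29 (adjusted p = 0.0631), and adjusted over the list alone 0 rose and 1 fell. Their median was -0.01 (camera adjusted p = 1.91e-06, adjusted p = 0.855 with an estimated correlation). For 46 oxidative phosphorylation genes, which make up the respiratory chain, 0 passed over all genes and 0 adjusted over the list alone. Their median and mean were 0.00, on the positive side, while the test pointed down (adjusted p = 0.00245), since it compares them with other genes, whose median was 0.06 (adjusted p = 0.903 with an estimated correlation).

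After cyclic loess between arrays PMA raised 14 genes and lowered 54, 28 of them among the 50, so the balance of rises and falls depended on the normalization. The count of 50 became 9 without control replicate 1, 29 without replicate 2, 25 without replicate 3 and 8 without replicate 4 of the controls; 129 without PA replicate 2 and 17 without PA replicate 4; 9, 15 and 11 without PMA replicates 1, 3 and 4 in turn; 24, 16, 21 and 30 without SA replicates 1, 2, 3 and 4 in turn; and 14 and 21 without OA replicates 1 and 3 in turn.

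SA raised 20 genes and lowered 11. The largest falls were Lcn2, an iron-binding acute phase protein secreted by adipocytes (-0.65 ± 0.09, adjusted p = 0.00404), Prg4, the joint lubricant lubricin (-0.60 ± 0.11, adjusted p = 0.0329) and Egr1 (-0.60 ± 0.07, adjusted p = 0.00023). Clk1, a kinase that regulates splicing, rose by 0.45 ± 0.07 (adjusted p = 0.0101), Ddit4, a stress-induced inhibitor of mTORC1, by 0.40 ± 0.07 (adjusted p = 0.0267), Il2ra, a chain of the interleukin 2 receptor, by 0.39 ± 0.07 (adjusted p = 0.0184), and Acta2, smooth muscle actin, by 0.36 ± 0.07 (adjusted p = 0.0389). Fmod rose by 0.39 and Fam171b by 0.42, while Sap30 fell by 0.51, Itih4, an acute phase serum protein, by 0.47 and Cox6a2, a cytochrome oxidase subunit, by 0.43. The median absolute change of the 31 genes was 0.34, and 3 exceeded 1.5-fold.

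Of these 12 genes, Lcn2 and Egr1 passed whichever array was left out. The adjusted p of Clk1 was 0.0516 and that of Prg4 0.124 at most (without SA replicates 3 and 4 in turn). For the others the largest was found without control replicate 1 (Ddit4, 0.0997; Itih4, 0.109) or without control replicate 4 (Il2ra and Sap30, 0.0852; Acta2 and Fam171b, 0.169; Cox6a2, 0.187; Fmod, 0.201).

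By camera 5 lists of lipid metabolism ranked above the other genes with SA, without a single member that passed over all genes, and none of them passed with an estimated correlation. Of 22 mitochondrial fatty acid oxidation genes 0 passed, with Crat, carnitine acetyltransferase, at 0.19 and Cpt1a, the gate of fatty acid entry into mitochondria, at 0.15. The count adjusted over the list alone was 3 higher and 0 lower (camera adjusted p = 0.00123, adjusted p = 0.567 with an estimated correlation). Of 20 cholesterol synthesis and uptake genes 0 passed, with Sqle, squalene epoxidase, at 0.22, and adjusted over the list alone 3 rose and 0 fell (camera adjusted p = 0.000287, adjusted p = 0.497 with an estimated correlation). Of 26 PPAR target genes 0 passed, with Plin1, the main lipid droplet coat of adipocytes, at 0.20 (adjusted p = 0.0739) and Pck1, a gluconeogenic and glyceroneogenic enzyme, at 0.19. The members past the threshold adjusted over the list alone were 3 higher and 0 lower (camera adjusted p = 0.0261, adjusted p = 0.497 with an estimated correlation). Of 19 de novo lipogenesis genes 0 passed, with Acss2 at 0.19, and adjusted over the list alone 2 rose and 0 fell (camera adjusted p = 0.0234, adjusted p = 0.567 with an estimated correlation). Of 27 genes of triglyceride synthesis, storage and lipolysis 0 passed, with Cidea, a lipid droplet protein, at 0.31. The members adjusted over the list alone gave 2 higher and 0 lower (camera adjusted p = 0.0174, adjusted p = 0.567 with an estimated correlation). Of 22 adipocyte markers 0 passed, with Plin1 at 0.20 and Adig at -0.41, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.00426, adjusted p = 0.497 with an estimated correlation). Of 26 genes of glucose uptake, glycolysis and insulin signalling 0 passed, over all genes or adjusted over the list alone (median 0.06, camera adjusted p = 0.0324, adjusted p = 0.639 with an estimated correlation).

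Of 36 extracellular matrix genes 1 rose with SA (Acta2), 0 fell and 35 did not pass, Lox, a collagen crosslinker, being 0.23 higher. Genes adjusted over the list alone numbered 7 higher and 0 lower (camera adjusted p = 6.87e-08, adjusted p = 0.368 with an estimated correlation). Of 18 immediate early genes 0 rose, 1 fell (Egr1) and 17 did not pass, and adjusted over the list alone 1 rose and 4 fell (camera adjusted p = 0.00033, adjusted p = 0.497 with an estimated correlation). Of 27 integrated stress response genes 1 rose (Ddit4), 0 fell and 26 did not pass, although the list ranked below the other genes (median -0.01). With p adjusted over the list alone 1 rose and 4 fell (camera adjusted p = 0.0229, adjusted p = 0.586 with an estimated correlation). Of 22 NRF2 target genes 0 passed, with Abcc4, an efflux pump, at -0.25. When adjusted over the list alone there were 1 higher and 1 lower (camera adjusted p = 0.0227, downward, adjusted p = 0.567 with an estimated correlation). Of 39 ribosomal protein genes 0 passed, with Rps24 at -0.28, and adjusted over the list alone 0 rose and 2 fell (median -0.05, camera adjusted p = 9.25e-06, adjusted p = 0.513 with an estimated correlation).

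Cyclic loess between arrays gave 45 genes higher and 41 lower with SA, 30 of them among the 31. The count of 31 became 9, 9, 15 and 4 without control replicates 1, 2, 3 and 4 in turn; 59 without PA replicate 2; 18 without PMA replicate 3; 11, 5, 4 and 9 without SA replicates 1, 2, 3 and 4 in turn; and 15 and 18 without OA replicates 1 and 3 in turn.

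OA raised 86 genes and lowered 76. Lcn2 fell by 1.04 ± 0.10 on the log2 scale (adjusted p = 1.08e-05), from 9.11 in control cells to 8.07, and Egr1 fell by 0.74 ± 0.07 (adjusted p = 1.08e-05), from 8.34 in control cells. Fmod rose by 0.86 ± 0.09 (adjusted p = 1.3e-05) and Ogn, osteoglycin, a related matrix proteoglycan, by 0.56 ± 0.09 (adjusted p = 0.00419). Sfrp2 rose by 0.63 ± 0.11 (adjusted p = 0.00898) and Ptgs2, the inducible cyclooxygenase that makes prostaglandins, fell by 0.43 ± 0.08 (adjusted p = 0.0103). The median absolute change of the 162 genes was 0.31, and 9 exceeded 1.5-fold.

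Other large rises with OA were Scarna13, a small RNA of Cajal bodies (1.03, adjusted p = 0.0209), Hmgn5, a nucleosome-binding protein (0.58, adjusted p = 0.0348), and Adgrg6, an adhesion G protein-coupled receptor (0.55, adjusted p = 0.0172). Other large falls were Car6, a secreted carbonic anhydrase (-0.64, adjusted p = 0.0201), Prg4 (-0.63, adjusted p = 0.0177), Ifi27l2a, an interferon-induced gene (-0.60, adjusted p = 0.0117), and Znfx1 (-0.64, adjusted p = 0.000211), whose dimmer probe set went the other way (0.09). Lcn2, Egr1, Fmod, Ogn and Znfx1 passed whichever array was left out. Without OA replicate 1 the adjusted p was 0.125 for Scarna13, 0.145 for Hmgn5 and 0.0893 for Adgrg6. Without OA replicate 2 it was 0.0583 for Sfrp2 and 0.0769 for Ifi27l2a, and without OA replicate 3 it was 0.143 for Car6, 0.114 for Prg4 and 0.0755 for Ptgs2.

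**Figure D2:**
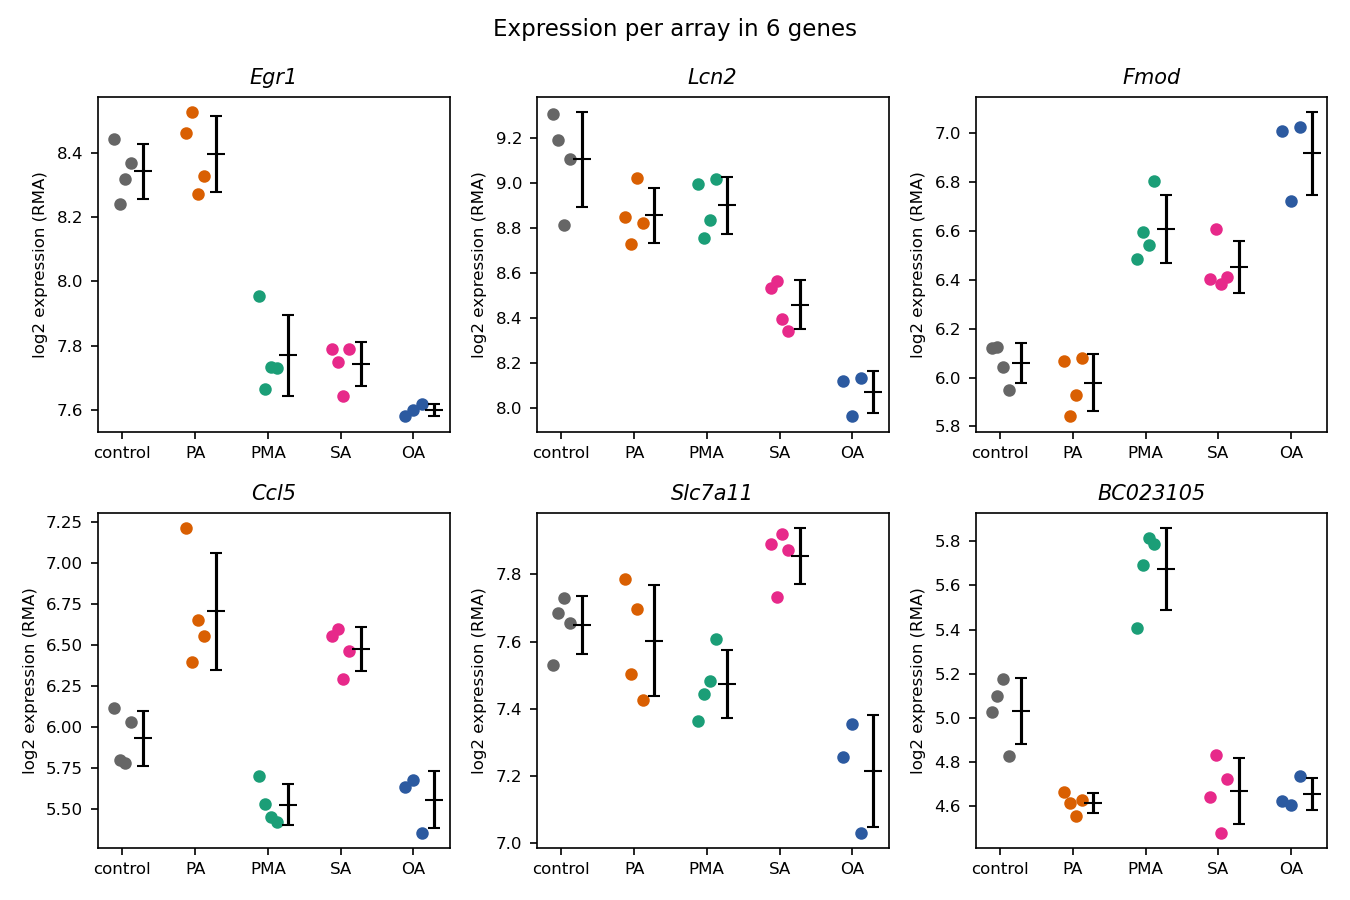
Log2 RMA expression on each array (dots) for 6 genes, with the mean and SD of each group (bars; n = 4, OA n = 3). Egr1 lies near 8.34 in control and 8.40 in PA cells and at 7.77 and 7.74 with PMA and SA, and Ccl5 at 6.71 and 6.48 with PA and SA against 5.53 and 5.56 with PMA and OA.

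By camera lists of inflammatory, stress and immediate early genes ranked below the other genes with OA, and none passed with an estimated correlation. Of 32 inflammatory cytokines, chemokines and acute phase genes 1 rose (Cxcl12, 0.28, adjusted p = 0.0117), 3 fell (Lcn2, Ptgs2 and Ccl7, the last by -0.31, adjusted p = 0.0383) and 28 did not pass. The count adjusted over the list alone was 2 higher and 6 lower (camera adjusted p = 8.58e-05, adjusted p = 0.205 with an estimated correlation). Among 18 immediate early genes 0 rose, 3 fell (Egr1, Junb by -0.29 and Ier2 by -0.45) and 15 did not pass, and adjusted over the list alone 1 rose and 6 fell (camera adjusted p = 9.3e-07, adjusted p = 0.205 with an estimated correlation). Of 27 integrated stress response genes 0 rose, 2 fell and 25 did not pass, the 2 being Slc7a11, the cystine importer (-0.44, adjusted p = 0.0193), and Ppp1r15a, which restores translation after stress (-0.28, adjusted p = 0.0193). Adjusted over the list alone 1 rose and 6 fell (camera adjusted p = 3.44e-05, adjusted p = 0.302 with an estimated correlation). Of 22 NRF2 target genes, which answer oxidative stress, 0 rose, 2 fell (Slc7a11 and Srxn1, sulfiredoxin, by -0.28) and 20 did not pass. The members past the threshold adjusted over the list alone were 1 higher and 4 lower (camera adjusted p = 0.00192, adjusted p = 0.331 with an estimated correlation). Of 24 endoplasmic reticulum chaperones and XBP1/ATF6 targets 0 rose, 1 fell (Sdf2l1, a chaperone cofactor, by -0.39) and 23 did not pass, with Hspa5 at -0.11, and adjusted over the list alone 0 rose and 1 fell (camera adjusted p = 0.0455, adjusted p = 0.468 with an estimated correlation). Of 31 interferon-stimulated genes 0 passed, over all genes or adjusted over the list alone, with Cxcl10 at -0.33 (median -0.05, camera adjusted p = 0.00467, adjusted p = 0.468 with an estimated correlation).

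Lists of matrix, adipocyte and lipid genes ranked above the other genes with OA, again without passing at an estimated correlation. Of 36 extracellular matrix genes 3 rose (Lox by 0.32, Thbs2, a matricellular protein, by 0.23 and Col6a1 by 0.20), 0 fell and 33 did not pass. The members adjusted over the list alone gave 7 higher and 0 lower (camera adjusted p = 6.56e-06, adjusted p = 0.248 with an estimated correlation). Of 22 preadipocyte and fibroblast markers 1 rose (Lox), 0 fell and 21 did not pass, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.0208, adjusted p = 0.468 with an estimated correlation). Of 22 adipocyte markers 1 rose (Pck1 by 0.21, adjusted p = 0.0488), 0 fell and 21 did not pass. Genes adjusted over the list alone numbered 3 higher and 1 lower (camera adjusted p = 0.00374, adjusted p = 0.319 with an estimated correlation). Of 26 PPAR target genes 2 rose (Cidea by 0.43 and Pck1), 0 fell and 24 did not pass, and adjusted over the list alone 4 rose and 0 fell (camera adjusted p = 0.0124, adjusted p = 0.312 with an estimated correlation). Of 22 mitochondrial fatty acid oxidation genes 1 rose (Crat by 0.24, adjusted p = 0.0295), 0 fell and 21 did not pass. When adjusted over the list alone there were 4 higher and 0 lower (camera adjusted p = 0.0059, adjusted p = 0.468 with an estimated correlation). Of 27 genes of triglyceride synthesis, storage and lipolysis 1 rose (Cidea), 0 fell and 26 did not pass, and adjusted over the list alone 2 rose and 0 fell (camera adjusted p = 0.0274, adjusted p = 0.468 with an estimated correlation).

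Of the remaining lists that passed with OA 4 ranked above the other genes, without a member past the threshold over all genes, and 1 below them. Of 19 de novo lipogenesis genes 0 passed. The count adjusted over the list alone was 2 higher and 0 lower (camera adjusted p = 0.0392, adjusted p = 0.468 with an estimated correlation). Of 20 cholesterol synthesis and uptake genes 0 passed, with Sqle at 0.25 (adjusted p = 0.0585), and adjusted over the list alone 1 rose and 0 fell (camera adjusted p = 0.0394, adjusted p = 0.474 with an estimated correlation). Of 26 genes of glucose uptake, glycolysis and insulin signalling 0 passed, over all genes or adjusted over the list alone (median 0.09, camera adjusted p = 0.00467, adjusted p = 0.468 with an estimated correlation). Of 30 mitosis genes 0 passed, although 26 were above control, with Mki67, a proliferation marker, at 0.35 (adjusted p = 0.0782). The members past the threshold adjusted over the list alone were 2 higher and 0 lower (median 0.15, camera adjusted p = 9.3e-07, adjusted p = 0.319 with an estimated correlation). Lower with OA were the ribosomal protein genes: of 39, 0 rose, 2 fell (Rps24 by -0.45, adjusted p = 0.00419, and Rpl11 by -0.31, adjusted p = 0.0167) and 37 did not pass, and adjusted over the list alone 0 rose and 4 fell (median -0.10, camera adjusted p = 2.94e-10, adjusted p = 0.248 with an estimated correlation).

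Among these list members Lcn2, Egr1 and Rps24 passed with OA whichever array was left out. The largest adjusted p without 1 array was 0.0755 (Cxcl12), 0.169 (Ccl7), 0.177 (Junb), 0.146 (Slc7a11), 0.214 (Srxn1), 0.191 (Thbs2), 0.247 (Col6a1) and 0.265 (Pck1) without OA replicate 3, 0.203 (Ier2), 0.111 (Ppp1r15a), 0.115 (Sdf2l1) and 0.0851 (Rpl11) without OA replicate 2, and 0.096 (Lox), 0.111 (Cidea) and 0.151 (Crat) without OA replicate 1. Cyclic loess between arrays gave 132 genes higher and 152 lower, 157 of them among the 162. The count of 162 became 65, 105, 64 and 33 without control replicates 1, 2, 3 and 4 in turn, and 46, 50 and 22 without OA replicates 1, 2 and 3 in turn.

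PMA, SA and OA changed 198 genes in any comparison with control, and 9 of them in all 3. The number in all 3 was 18 without PA replicate 2, and 1 to 8 when another array was left out. Higher were Fmod, Clk1, Arl14ep and Armcx2, and lower were Egr1, Sap30, Cnih4, Gm10548 and Med21, a subunit of the Mediator complex of transcription. Arl14ep, Cnih4 and Med21 fell outside the rule for named genes and were chosen after their values were seen. With PA the same genes stood at -0.08 for Fmod, -0.01 for Clk1, 0.06 for Arl14ep, 0.13 for Armcx2, 0.05 for Egr1, -0.18 for Sap30, -0.15 for Cnih4, -0.34 for Gm10548 and -0.18 for Med21, none past the threshold. SA and OA shared 11 rises and 9 falls, PMA and OA 13 and 12, and PMA and SA 4 and 5, with no gene called in opposite directions; independent lists would share 0.0914 and 0.0444, 0.165 and 0.0565, and 0.0383 and 0.00818 genes, numbers that leave out the controls shared by the acids. A test chosen after seeing the data took as many genes of smallest p as were called, in 100 simulations of unchanged groups against the same controls. The mean shared in the same direction was 6.20 for SA and OA (12 at most, against 20), 8.40 for PMA and OA (14 at most, against 25), 3.94 for PMA and SA (10 at most, against 9) and 1.51 for all 3 (6 at most, against 9). The overlap of PMA and SA thus lay within the simulated range. Leaving out 1 array moved the overlaps to between 4 and 41, 5 and 59, 1 and 18, and 1 and 18 genes.

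Across genes, which are not independent replicates, the log2 fold changes of SA and OA correlated at 0.724, those of PMA and SA at 0.587 and those of PMA and OA at 0.584. Simulated unchanged groups against shared controls gave 0.462, 0.499 and 0.462, and with the controls split between the acids the values were 0.368, 0.217 and 0.266. The simulation gave every group the same spread, estimated with the wider PA arrays included. It may thus overstate what the controls (SD from their group mean 0.0816) add. For PA the correlations were 0.401 with PMA, 0.346 with SA and 0.149 with OA, below the simulated 0.500, 0.499 and 0.461. The simulation does not carry the wider spread of the PA arrays, which lowers a correlation. These values thus do not show that PA shared less than the controls alone would give. The covariances, which a wide spread does not lower, were 0.00381, 0.00320 and 0.00165, above the simulated 0.00301 and 0.00300 for PMA and SA and below the simulated 0.00300 for OA. With the controls split the correlations of PA were 0.148 with PMA, 0.104 with SA and -0.0215 with OA. The covariances were then 0.00157, 0.000961 and -0.000585.

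**Figure D3:**
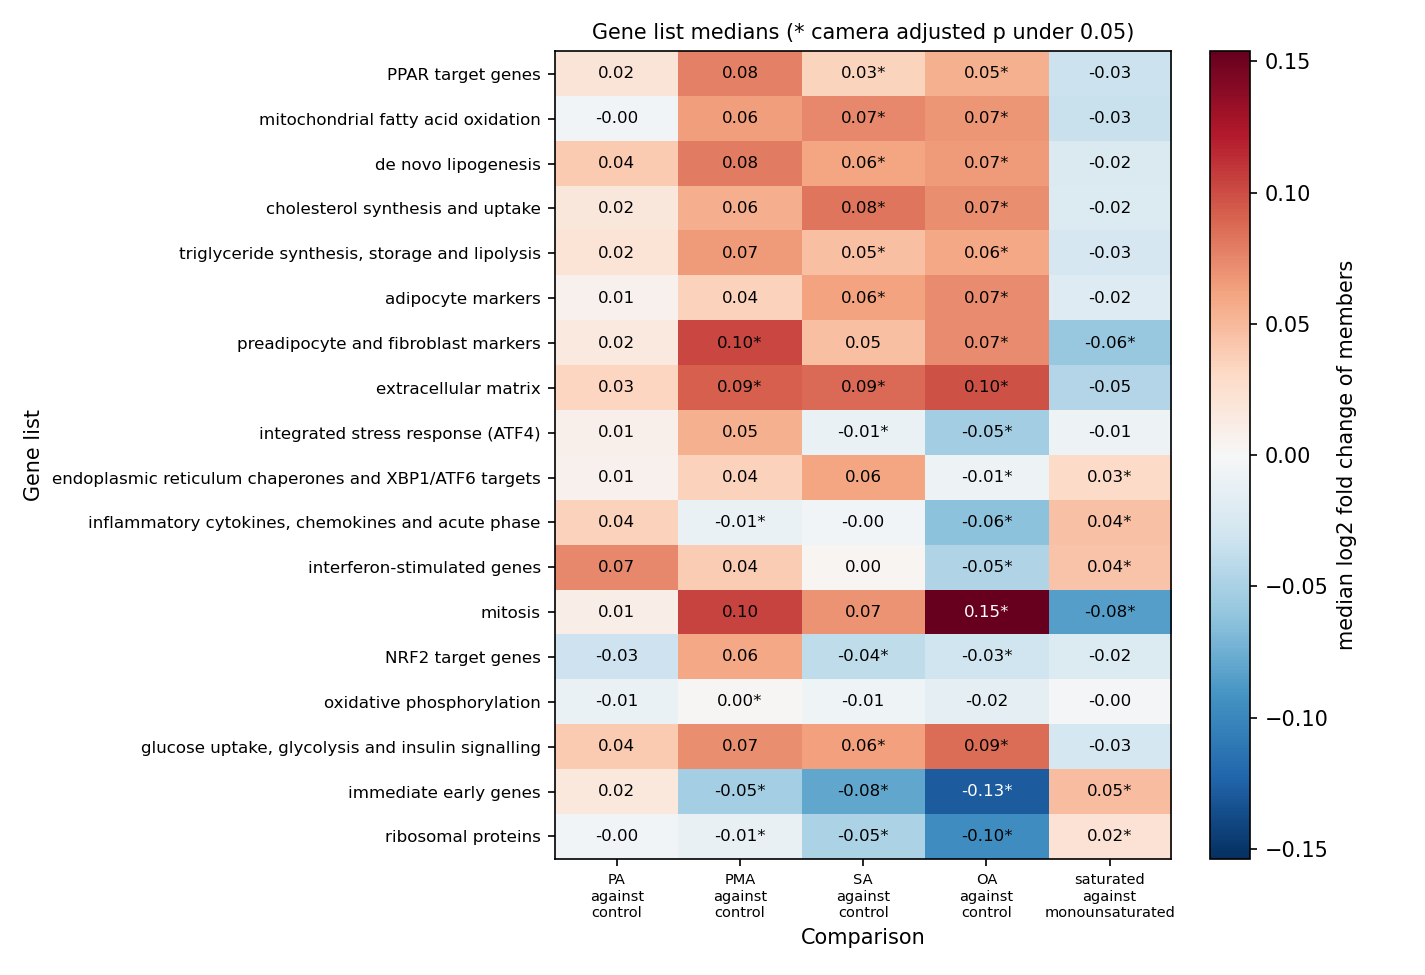
Median log2 fold change of the members of each gene list (colour and number) in each acid against control and in the saturated against the monounsaturated acids; an asterisk marks a camera adjusted p under 0.05. With OA the immediate early genes stand at -0.13, the ribosomal protein genes at -0.10 and the mitosis genes at 0.15, and with PA no list is marked.

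The saturated acids PA and SA together (8 arrays) gave higher expression of 5 of 32 inflammatory genes, and lower of 1, than the monounsaturated PMA and OA (7 arrays). This sets the classes against each other and not against control. Ccl5 was 1.05 ± 0.09 higher (adjusted p = 4.51e-06). Also higher were Hp, haptoglobin, an acute phase protein (0.33 ± 0.05, adjusted p = 0.00241), Wfdc21, a secreted protein of the innate response (0.36 ± 0.04, adjusted p = 8.88e-05), and Hmga2, a chromatin protein of growing mesenchymal cells (0.42 ± 0.06, adjusted p = 0.000978). Lower with the saturated acids were Agtr2, the angiotensin II type 2 receptor (-0.57 ± 0.08, adjusted p = 0.000708), Sfrp2 (-0.54 ± 0.07, adjusted p = 0.000488) and Clec3b, tetranectin, a plasminogen-binding matrix protein (-0.40 ± 0.06, adjusted p = 0.000937). In all 26 genes were higher and 78 lower, with a median absolute difference of 0.28. The arrays of the 2 classes did not overlap in 30 of these 104 genes. By pair, PA against PMA gave 20 genes higher and 161 lower, and SA against OA 6 higher and 0 lower. The count is thus not a difference seen in both pairs.

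Ptprn, a protein of secretory granules (0.30), and Tes, a focal adhesion protein (0.29), were also higher with the saturated acids, and Sema3c, a secreted guidance signal (-0.32), Cpe (-0.31) and Chst2, a sulfotransferase (-0.30, adjusted p = 0.0145), were lower. These 12 genes passed whichever array was left out. Of the panel, Ccl2 passed and the other genes did not. The 95% interval of saturated minus monounsaturated reached from -0.09 to 0.06 for Scd1, from -0.09 to 0.05 for Plin2, from -0.08 to 0.09 for Fabp4 and from -0.16 to 0.01 for Cd36. For Cpt1a (-0.12, adjusted p = 0.19) it reached from -0.20 to -0.04 and for Fads2, a desaturase (-0.08, adjusted p = 0.366), from -0.15 to -0.01.

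Of 32 inflammatory cytokines, chemokines and acute phase genes 5 were higher and 1 lower with the saturated acids and 26 did not pass. Higher were Ccl5, Ccl7 (0.29, adjusted p = 0.00228), Hp, Ccl2, the main monocyte chemokine (0.33, adjusted p = 0.0153), and Ptgs2 (0.30, adjusted p = 0.00519), the last named after its value was seen, and lower was Cxcl12 (-0.24, adjusted p = 0.000937). Of the higher genes only Ccl5 lay above every control array with both PA and SA. For Ccl7 the arrays lay at 8.15 to 8.21 with PA and 8.04 to 8.26 with SA, and at 8.14 to 8.40 in controls. With PMA they lay at 7.753 to 7.845 and with OA at 7.87 to 8.09. For Ptgs2 they lay at 7.11 to 7.51 with PA, 7.26 to 7.40 with SA and 7.26 to 7.39 in controls. With PMA (7.10 to 7.23) and OA (6.80 to 6.97) they lay lower. With p adjusted over the list alone 6 were higher and 2 lower (median 0.04, camera adjusted p = 1.12e-06), and the shift also passed with an estimated correlation (adjusted p = 0.0461). Of 18 immediate early genes 2 were higher (Egr1 by 0.38, adjusted p = 0.000315, and Junb by 0.25, adjusted p = 0.00753), 0 lower and 16 did not pass. The members adjusted over the list alone gave 3 higher and 0 lower (camera adjusted p = 1.92e-05, adjusted p = 0.343 with an estimated correlation). The Egr1 difference came from PA and not from SA. Against control Egr1 stood at 0.05 with PA, -0.60 with SA, -0.57 with PMA and -0.74 with OA. Of 24 endoplasmic reticulum chaperones and XBP1/ATF6 targets 1 was higher (Sec61b, part of the translocation channel, by 0.25), 0 lower and 23 did not pass, and adjusted over the list alone 5 were higher and 0 lower (camera adjusted p = 0.000444, adjusted p = 0.508 with an estimated correlation). Of 31 interferon-stimulated genes 1 was higher (Rsad2, viperin, by 0.31, adjusted p = 0.0354), 0 lower and 30 did not pass. Genes adjusted over the list alone numbered 3 higher and 0 lower (camera adjusted p = 0.00268, adjusted p = 0.793 with an estimated correlation). Without OA replicate 3 the adjusted p was 0.0811 for Ccl2, 0.0892 for Sec61b and 0.104 for Rsad2.

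By camera the mitosis and fibroblast lists ranked below the other genes with the saturated acids, without a member that passed over all genes, and neither passed with an estimated correlation. Of 30 mitosis genes 0 passed, although 28 were lower, with Ccna2, cyclin A2, at -0.22 (adjusted p = 0.111), and adjusted over the list alone 0 were higher and 4 lower (camera adjusted p = 2.4e-05, adjusted p = 0.793 with an estimated correlation). Of 22 preadipocyte and fibroblast markers 0 passed, with Dlk1 at -0.15. When adjusted over the list alone there were 0 higher and 2 lower (camera adjusted p = 0.0126, adjusted p = 0.793 with an estimated correlation). Of 39 ribosomal protein genes 0 passed, with Rpl11 at 0.16, and adjusted over the list alone 2 were higher and 0 lower (camera adjusted p = 0.000218, adjusted p = 0.793 with an estimated correlation). With cyclic loess between arrays there were 57 genes higher and 63 lower, 83 of them among the 104. The count of 104 became 67 without PA replicate 4 and 46 without OA replicate 3.

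At 16 carbons, PA gave higher expression of the chemokines Ccl5 and Ccl2 and of Egr1 than PMA, and lower expression of the matrix proteoglycans Fmod and Ogn. Ccl5 was 1.18 ± 0.13 higher (adjusted p = 4.39e-05), Egr1 0.63 ± 0.07 higher (adjusted p = 4.39e-05), Hp 0.44 ± 0.07 higher (adjusted p = 0.00369), Ccl2 0.47 ± 0.09 higher (adjusted p = 0.011) and Ccn1, a matricellular protein induced by growth signals, 0.49 ± 0.09 higher (adjusted p = 0.0067). BC023105 was lower with PA by -1.06 ± 0.09 (adjusted p = 8.35e-07), Agtr2 by -0.74, Sfrp2 by -0.66, Fmod by -0.63, Ogn by -0.62 and Plagl1 by -0.56. Wfdc21 was 0.49 higher, and so was Znfx1 by 0.62, whose dimmer probe set went the other way (-0.16). Cpt1a was lower with PA by -0.22 (adjusted p = 0.0422, and 0.145 without PMA replicate 4). The other genes named here passed whichever array was left out. In all 20 genes were higher and 161 lower. The shared spread may understate that of PA, so these p-values may be too small.

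Of 32 inflammatory cytokines, chemokines and acute phase genes 4 were higher with PA than with PMA (among them Ccl5, Hp and Ccl7, 0.38), 1 lower (Cxcl12, -0.26) and 27 did not pass. The count adjusted over the list alone was 7 higher and 3 lower (camera adjusted p = 0.00275, adjusted p = 0.526 with an estimated correlation). Of 18 immediate early genes 2 were higher (Egr1, and Junb by 0.30, adjusted p = 0.022 but 0.0905 without PMA replicate 4), 0 lower and 16 did not pass, and adjusted over the list alone 3 were higher and 0 lower (camera adjusted p = 0.000295, adjusted p = 0.526 with an estimated correlation). Of 22 preadipocyte and fibroblast markers 0 passed, with Dlk1 at -0.23. The members past the threshold adjusted over the list alone were 0 higher and 1 lower (camera adjusted p = 0.0231, adjusted p = 0.862 with an estimated correlation). Of 30 mitosis genes 0 passed, over all genes or adjusted over the list alone (median -0.12, camera adjusted p = 0.0357, adjusted p = 0.862 with an estimated correlation). Without PA replicates 2 and 4 the direction of the mitosis list reversed (adjusted p = 0.963). None of 39 ribosomal protein genes passed either way (median 0.01, camera adjusted p = 0.0272, adjusted p = 0.862 with an estimated correlation). Cyclic loess between arrays gave 55 genes higher and 59 lower with PA than with PMA, 75 of them among the 181. The count of 181 became 447, 638 and 49 without PA replicates 1, 3 and 4 in turn, and 77, 89 and 74 without PMA replicates 1, 3 and 4 in turn.

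At 18 carbons, SA and OA differed in 6 genes, all higher with SA. They were Ccl5 (0.92 ± 0.14, adjusted p = 0.0116), Slc7a11 (0.64 ± 0.09, adjusted p = 0.00548), Ereg, the growth factor epiregulin (0.53 ± 0.08, adjusted p = 0.0139), Hmga2 (0.52 ± 0.09, adjusted p = 0.0368), Ptgs2 (0.43 ± 0.08, adjusted p = 0.0488) and Bcat1, which breaks down branched-chain amino acids (0.39 ± 0.07, adjusted p = 0.0337). Without OA replicate 3 none of the 6 passed, with adjusted p = 0.138 for Slc7a11, 0.211 for Ccl5 and Ereg, 0.587 for Hmga2, 0.692 for Ptgs2 and 0.503 for Bcat1, and the limma count was 0. The count was 3 without control replicate 3, control replicate 4 or PMA replicate 3, 1 without SA replicate 1 and 2 without SA replicate 4. In all 451 genes had an unadjusted p under 0.05, and cyclic loess between arrays gave 6 higher and 1 lower.

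Of 32 inflammatory cytokines, chemokines and acute phase genes 2 were higher with SA than with OA (Ccl5 and Ptgs2), 0 lower and 30 did not pass, and adjusted over the list alone 5 were higher and 1 lower. The shift (median 0.07, camera adjusted p = 6.94e-08) also passed with an estimated correlation (adjusted p = 0.028), but not when only the 7 arrays of SA and OA were used (adjusted p = 0.0818 with an estimated correlation), a test chosen after seeing the data. Of 24 endoplasmic reticulum chaperones and XBP1/ATF6 targets 0 passed, with Sdf2l1 at 0.27, and adjusted over the list alone 2 were higher and 0 lower (camera adjusted p = 6.94e-08, adjusted p = 0.0987 with an estimated correlation). Of 27 integrated stress response genes 1 was higher (Slc7a11), 0 lower and 26 did not pass. The members adjusted over the list alone gave 1 higher and 0 lower (camera adjusted p = 0.0044, adjusted p = 0.694 with an estimated correlation). Of 31 interferon-stimulated genes 0 passed, with Rsad2 at 0.42, and adjusted over the list alone 1 was higher and 0 lower (camera adjusted p = 3.3e-05, adjusted p = 0.631 with an estimated correlation). No gene of 30 for mitosis (median -0.10, camera adjusted p = 2.73e-07, adjusted p = 0.631 with an estimated correlation), 18 immediate early (median 0.05, camera adjusted p = 0.0044, adjusted p = 0.631 with an estimated correlation) or 39 ribosomal protein (median 0.04, camera adjusted p = 0.000176, adjusted p = 0.709 with an estimated correlation) genes passed, over all genes or adjusted over the list alone.

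Between the saturated acids, PA left Egr1 and the phosphatase Dusp6 higher than SA, and the matrix proteoglycan Ogn lower. Egr1 was 0.65 ± 0.07 higher with PA (adjusted p = 5.21e-05), and Dusp6, a phosphatase that ERK signalling induces, 0.41 ± 0.06 higher (adjusted p = 0.00587). P4ha3, a collagen prolyl hydroxylase (-0.48 ± 0.06, adjusted p = 0.00133), Ogn (-0.52 ± 0.08, adjusted p = 0.00587) and Clk1 (-0.46 ± 0.07, adjusted p = 0.00587) were lower. These 5 passed whichever array was left out. Chchd10, a mitochondrial protein (0.52), the transcript 5730408K05Rik (0.57), Bbc3, the cell death protein PUMA (0.41), and Znfx1 (0.37) were higher, and Gys2, glycogen synthase (-0.53), Cpa5 (-0.48) and Fmod (-0.47) lower. Their adjusted p rose without SA replicate 1 to 0.176 for 5730408K05Rik, 0.223 for Bbc3, 0.149 for Znfx1 and 0.123 for Gys2 and Cpa5, to 0.0878 for Chchd10 without SA replicate 3 and to 0.0812 for Fmod without SA replicate 2. The dimmer probe set of Znfx1 went the other way (-0.15). In all 8 genes were higher and 19 lower. Here too the shared spread may understate that of PA.

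Among 18 immediate early genes 1 was higher with PA than with SA (Egr1), 0 lower and 17 did not pass. Genes adjusted over the list alone numbered 5 higher and 0 lower (camera adjusted p = 0.00544, adjusted p = 0.679 with an estimated correlation). Of 36 extracellular matrix genes 0 passed, with Lox at -0.27, and adjusted over the list alone 0 were higher and 8 lower (camera adjusted p = 0.000147, adjusted p = 0.679 with an estimated correlation). Of 22 mitochondrial fatty acid oxidation genes 0 passed, with Cpt1a at -0.19. When adjusted over the list alone there were 0 higher and 3 lower (camera adjusted p = 0.000551, adjusted p = 0.679 with an estimated correlation). Of 20 cholesterol synthesis and uptake genes 0 passed, with Nsdhl at -0.26, and adjusted over the list alone 0 were higher and 1 lower (camera adjusted p = 0.000372, adjusted p = 0.679 with an estimated correlation). The lists of adipocyte markers (median -0.06, camera adjusted p = 0.0264, adjusted p = 0.679 with an estimated correlation; 0 of 22 past the threshold adjusted over the list alone) and mitosis genes (median -0.06, camera adjusted p = 0.0145, adjusted p = 0.83 with an estimated correlation; 1 of 30 lower adjusted over the list alone) ranked below the other genes. The ribosomal protein list ranked above them (median 0.04, camera adjusted p = 0.0391, adjusted p = 0.83 with an estimated correlation), with 0 of 39 past the threshold over all genes and 1 adjusted over the list alone. With cyclic loess between arrays there were 17 genes higher and 26 lower, 25 of them among the 27. The count of 27 became 499 and 11 without PA replicates 1 and 4 in turn, and 11 and 9 without SA replicates 1 and 2 in turn.

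Between the monounsaturated acids, PMA left more Lcn2 (0.83 ± 0.10, adjusted p = 0.000257), Abcc4 (0.51 ± 0.07, adjusted p = 0.000983) and BC023105 (1.02 ± 0.09, adjusted p = 6.92e-06) than OA, and less B3galt2, a galactosyltransferase (-0.43 ± 0.06, adjusted p = 0.00191). These 4 passed whichever array was left out. Prg4 (0.72), Chchd10 (0.58) and Trib3, a pseudokinase of the stress response (0.41), were higher with adjusted p = 0.026 each, and Pnpla3, a lipid droplet hydrolase, was lower (-0.30, adjusted p = 0.0312). Without OA replicate 3 the adjusted p was 0.282 for Prg4 and Chchd10 and 0.306 for Pnpla3, and without OA replicate 2 it was 0.297 for Trib3. In all 8 genes were higher and 2 lower.

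By camera the integrated stress response and NRF2 lists ranked above the other genes in PMA against OA, with 1 member each past the threshold, and neither passed with an estimated correlation. Of 27 integrated stress response genes 1 was higher (Trib3), 0 lower and 26 did not pass, although 25 were on the higher side. The count adjusted over the list alone was 10 higher and 0 lower (median 0.14, camera adjusted p = 2.91e-08, adjusted p = 0.221 with an estimated correlation). Of 22 NRF2 target genes 1 was higher (Abcc4), 0 lower and 21 did not pass, and adjusted over the list alone 4 were higher and 0 lower (camera adjusted p = 0.000143, adjusted p = 0.495 with an estimated correlation). Of 31 interferon-stimulated genes 0 passed, with Tap1 at 0.36. The members past the threshold adjusted over the list alone were 1 higher and 0 lower (camera adjusted p = 0.0144, adjusted p = 0.717 with an estimated correlation). Of 22 adipocyte markers 0 passed, with Lep, leptin, at -0.35 (adjusted p = 0.0738), and adjusted over the list alone 0 were higher and 1 lower (camera adjusted p = 1.3e-05, adjusted p = 0.221 with an estimated correlation). For 36 extracellular matrix genes 0 passed, adjusted over the list alone 0 were higher and 2 lower, and the median (0.02) differed in sign from the mean (-0.02) and the test (camera adjusted p = 0.0144, adjusted p = 0.717 with an estimated correlation). Lists without a member past the threshold, over all genes or adjusted over the list alone, were mitosis (median -0.08, camera adjusted p = 5.95e-06), mitochondrial fatty acid oxidation (-0.01, 0.0128) and cholesterol synthesis and uptake (-0.01, 0.0325), all pointing down, and ribosomal proteins (0.06, 0.0133), pointing up. For these 4 the adjusted p = 0.717 with an estimated correlation.

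Cyclic loess between arrays gave 11 genes higher and 9 lower with PMA than with OA, 10 of them among the 10. The count of 10 became 4, 19, 5 and 4 without PMA replicates 1, 2, 3 and 4 in turn, and 5 and 4 without OA replicates 2 and 3 in turn.

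The effect of the double bond differed between 16 and 18 carbons in 1 gene, BC023105 (interaction -1.07 ± 0.13, adjusted p = 0.000611, and at most 0.00637 when an array was left out). It is among the dimmest genes, and with these left out 0 genes passed. It stood at 4.62 with PA against 5.68 with PMA, and at 4.67 with SA against 4.66 with OA. With limma 0 genes were higher and 986 had an unadjusted p under 0.05. Of 27 integrated stress response genes and 22 NRF2 target genes 0 passed over all genes, and adjusted over the list alone 0 were higher and 1 and 2 lower. Both lists ranked below the other genes (medians -0.09 and -0.07, camera adjusted p = 0.0301 each, adjusted p = 0.993 with an estimated correlation).

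The mean of the 4 acids differed from control in 37 genes, 19 higher and 18 lower. Egr1 fell by 0.46 ± 0.05 (adjusted p = 0.000365), Lcn2 by 0.53 ± 0.07 (adjusted p = 0.00232) and the transcript Gm10548 by 0.39 ± 0.06 (adjusted p = 0.00334), and these 3 passed whichever array was left out. Higher were Scarna13 (0.80, adjusted p = 0.0322), Fmod (0.43, adjusted p = 0.00422), Clk1 (0.31, adjusted p = 0.0187), Stat5a, a transcription factor of cytokine signalling (0.27, adjusted p = 0.00839), Armcx2 (0.26, adjusted p = 0.0203) and Ctdsp1, a phosphatase of RNA polymerase II (0.25, adjusted p = 0.0458). Also lower were Sap30 (-0.43), Rpa3 (-0.42) and Znfx1 (-0.37), with the dimmer probe set of Znfx1 at 0.05. A mean over the 4 acids need not be a change by each. With PA, Egr1 stood at 0.05, Fmod at -0.08 and Clk1 at -0.01 against control. Gm10548 (-0.34), Sap30 (-0.18) and Armcx2 (0.13) went the way of the mean with PA, without passing. Without control replicate 4 the adjusted p was 0.189 for Scarna13, 0.0633 for Fmod and Znfx1, 0.0884 for Stat5a, 0.147 for Armcx2, 0.263 for Ctdsp1 and 0.092 for Sap30 and Rpa3, and without control replicate 1 it was 0.0929 for Clk1.

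Of 36 extracellular matrix genes 1 rose over the 4 acids (Col6a1, 0.17, adjusted p = 0.0458 but 0.189 without control replicate 4), 0 fell and 35 did not pass. The members adjusted over the list alone gave 9 higher and 0 lower (camera adjusted p = 8.48e-05, adjusted p = 0.41 with an estimated correlation). Of 39 ribosomal protein genes 0 rose, 1 fell (Rps24, -0.27, adjusted p = 0.0322 but 0.168 without control replicate 4) and 38 did not pass, and adjusted over the list alone 0 rose and 2 fell (camera adjusted p = 6.46e-08, adjusted p = 0.41 with an estimated correlation). Of 18 immediate early genes 0 rose, 1 fell (Egr1) and 17 did not pass. Genes adjusted over the list alone numbered 1 higher and 2 lower (camera adjusted p = 3.01e-05, adjusted p = 0.41 with an estimated correlation). Of 32 inflammatory cytokines, chemokines and acute phase genes 0 rose, 1 fell (Lcn2) and 31 did not pass, and adjusted over the list alone 2 rose and 2 fell; their median (0.00) was on the positive side, against the mean (-0.03) and the test (camera adjusted p = 0.0177, adjusted p = 0.41 with an estimated correlation). Without a member past the threshold, over all genes or adjusted over the list alone, were de novo lipogenesis (median 0.07, camera adjusted p = 0.0411), glucose uptake, glycolysis and insulin signalling (0.07, 0.0349), NRF2 target genes (-0.03, 0.0349) and oxidative phosphorylation (-0.01, 0.0293), and for these 4 the adjusted p = 0.681 with an estimated correlation. Cyclic loess between arrays gave 47 genes higher and 86 lower, 36 of them among the 37. The count of 37 became 11, 23 and 4 without control replicates 1, 3 and 4 in turn, 92 and 21 without PA replicates 2 and 4 in turn, 23 without PMA replicate 4, 19, 22 and 20 without SA replicates 1, 2 and 3 in turn, and 24 and 23 without OA replicates 1 and 3 in turn.

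Markers of other cell types passed in none of the 11 comparisons, and their smallest camera adjusted p was 0.083 for 15 macrophage markers (PMA against OA), 0.163 for 12 endothelial markers (PA against SA), 0.0817 for 13 muscle markers (PA against PMA) and 0.271 for 10 osteoblast and chondrocyte markers (SA against control). Other lists without a pass were those of peroxisomal fatty acid oxidation (smallest camera adjusted p = 0.322), fatty acid uptake, activation and binding (0.659), desaturases and elongases (0.0547), LXR target genes (0.389), thermogenic adipocyte markers (0.06), DNA replication (0.258), p53 target genes (0.211) and ceramide and sphingolipid metabolism (0.0751). Over all comparisons 80 list shifts passed, and 2 of them, those of the inflammatory list in the saturated acids and in SA against OA, passed with an estimated correlation. The latter did not with the SA and OA arrays alone (adjusted p = 0.0818).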

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

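Some tests in this part were chosen only after the result was seen: leaving out PA replicate 1 or 2, cyclic loess for PA, for the ribosomal list and for the inflammatory list, the matched lists and the permutation of the ribosomal genes, and the inflammatory list in SA against OA, with all arrays and with those of SA and OA alone.

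No gene passed in PA against control. A single divergent array, PA replicate 2, and a difference between arrays that depends on the level are argued against: without PA replicate 2 the count was 1 (129, 59 and 243 for PMA, SA and OA in the same fit), and after cyclic loess it was 0 (68, 86 and 284). PA replicate 1 stays open, since without it 510 genes passed (60, 30 and 169 for the other acids), of a median level of 5.42 against 5.97 over all genes, and 257 with cyclic loess as well, 210 of them shared; yet over the 230 genes called for the mean of the other 3 acids its mean signed change, 0.0779, was near the 0.0931, 0.0854 and 0.105 of replicates 2, 3 and 4. A smaller response to PA stays open too. Over those 230 genes the signed change with PA was 0.353 ± 0.0228 of that with the other 3 acids. It was 0.802 (34 genes), 1.00 (20 genes) and 1.36 (5 genes) for PMA, SA and OA, each over a different set of genes called for the mean of its own other 3. The error holds only the spread of the 4 PA arrays, and not that of the controls or the other acids. The genes were called against the same controls, so control error alone can raise the ratio above 0. Both explanations, PA replicate 1 and a smaller response, may hold.

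The ribosomal protein genes were lower with OA (median -0.10). Among highly expressed genes the median change with OA went from -0.05 in the 629 of shortest span to 0.10 in the 627 of longest span (-0.04 to 0.06 with SA), ribosomal genes are short, and no other list was matched on span. As the whole cause this trend with gene span is argued against for OA: lists matched on level had a median of 0.04, lists matched on level and span -0.02 (95% between -0.06 and 0.01), and the ribosomal median lay at percentile 0 of 10000 of the latter (2.23 with SA, and 0.14 with PMA, where the list stood at -0.01 against 0.03). A trend with level left in the deposited values is argued against as well, since after cyclic loess the median was still -0.10. The loess started from values already normalised and cannot undo the authors' normalization, which stays open. Per array, the mean of the list with OA minus that in control cells was -0.10 (exact permutation p = 0.0286, the smallest that 35 assignments can give). By the same permutation it was -0.06 with SA (p = 0.0286), -0.02 with PMA (p = 0.229) and 0.00 with PA (p = 1). A response of the ribosomal genes to OA is a candidate explanation, as a hypothesis found on the same data, and the list did not pass with an estimated correlation (adjusted p = 0.248).

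The inflammatory list was higher with the saturated than with the monounsaturated acids (camera adjusted p = 1.12e-06, and 0.0461 with an estimated correlation). The divergent PA arrays are argued against, since the list also passed in SA against OA, where PA enters the spread but not the means (adjusted p = 6.94e-08), and with the 7 arrays of SA and OA alone (adjusted p = 5.85e-08, though 0.0818 with an estimated correlation). Dependence on a single gene, Ccl5, stays open. Without it the list of 31 genes had p = 0.00347 with an estimated correlation (camera), under the bound of 0.05 written down before. Adjusted over the lists this was 0.104, against 0.0461 with Ccl5, so the list no longer passed at the threshold used above. A trend with level left in the deposited values is argued against by a camera adjusted p of 1.60e-06 after cyclic loess. The authors' normalization itself could not be tested this way and stays open. In PA against PMA, the other pair that differs by the double bond, the list passed at the preset but not at an estimated correlation. An effect of the double bond on inflammatory genes stays a hypothesis, and the labels give no batch against which to test it.

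Chance as the source of the counts was weighed against a bound. Under 5 in 100 splits of the same arrays, the real one included, were to give as many genes. It was met for PMA (1 of 35 splits, 50 genes, highest other 0) and SA (1 of 35, 31 genes, highest other 2). So it was for OA (1 of 35, 162 genes, highest other 2) and SA against OA (1 of 35, 6 genes, highest other 0). PMA against OA met it too (1 of 35, 10 genes, highest other 3). A share of 1 of 35 is the smallest that 35 splits can give, and it was not adjusted over the comparisons. Without OA replicate 3 the count of SA against OA was 0. With 2 of 100 splits each the bound was met for saturated against monounsaturated acids (104 genes, highest other 1054). The same held for the interaction (1 gene, highest other 1) and the mean of the 4 acids (37 genes, highest other 2228). In these a random split gave as many genes or more, so chance is not excluded. PA against PMA missed the bound (2 of 35, 181 genes, highest other 507). PA against SA did too (2 of 35, 27 genes, highest other 1767). For PA the splits say nothing about chance, since no split can fall below its count of 0 (35 of 35 splits, highest other 148). Splits with several times the real count point to a structure of the arrays other than the groups. In PA against PMA that split set PA replicates 1 and 3 with PMA replicates 2 and 3, and in PA against SA it set PA replicate 1 with SA replicates 1, 2 and 3.

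In 17 of 340 groups of 4 arrays tested, or 5%, which is the share chance gives, 1 array lay apart from the others, measured by its gap to the nearest array as a share of the range. In the controls these were Fads2 (0.934), Prg4 (0.920) and Gys2 (0.843) in replicate 2, Hmga2 in replicate 1 (0.902) and Agtr2 in replicate 3 (0.887). With PA they were Elovl6 (0.888) and Col1a1 (0.901) in replicate 2 and Cox6a2 in replicate 4 (0.848). With PMA they were the interquartile range of replicate 1 (0.832), Scarna13 in replicate 2 (0.863), and Gys2 (0.859) and P4ha3 (0.872) in replicate 1. With SA they were Srebf1 (0.854) and Insig1 (0.885) in replicate 4, Fmod in replicate 2 (0.878), and Chst2 (0.951) and Ctdsp1 (0.880) in replicate 3.

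The effect of the double bond differed between chain lengths for BC023105 (interaction -1.07, adjusted p = 0.000611) and for the integrated stress response and NRF2 lists (adjusted p = 0.0301 each, and 0.993 with an estimated correlation). Among 14338 probe sets with no gene symbol or several, which the comparisons of genes do not use, 4 passed with PMA, 17 with SA, 33 with OA and 44 for the mean of the 4 acids.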

How the results depend on the processing

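Array quality weights, leaving out PA replicates 2 and 4, leaving out PMA replicates 1 and 4, cyclic loess with PA replicate 1 left out, and the inflammatory list with only the SA and OA arrays were tests chosen after seeing the data. Of 132 values of named genes past the threshold, 59 stayed past it whichever array was left out, 100 with the replicate number as a block, 125 with cyclic loess, 84 with only the groups compared in the fit and 130 with weights, and 0 reversed. Of 80 list shifts past the threshold 74 stayed with weights, 72 with cyclic loess, 65 without the dimmest genes, 75 with the block, 68 without PA replicates 2 and 4, 69 without PMA replicates 1 and 4 and 2 with an estimated correlation, of which the inflammatory list in SA against OA no longer passed with only the SA and OA arrays (adjusted p = 0.0818). Counts of genes past the threshold when 1 array was left out ran from 0 to 510 for PA, 8 to 129 for PMA, 4 to 59 for SA, 22 to 243 for OA, 46 to 130 for saturated against monounsaturated acids, 49 to 638 for PA against PMA, 0 to 7 for SA against OA, 9 to 499 for PA against SA, 4 to 19 for PMA against OA, 1 to 1 for the interaction and 4 to 92 for the mean of the 4 acids. With the dimmest genes left out, where fewer genes share the adjustment, they were 199 for PMA, 48 for SA, 255 for OA, 163 for saturated against monounsaturated, 430 for PA against PMA, 41 for PA against SA, 16 for PMA against OA, 0 for the interaction and 110 for the mean. Testing every probe set gave 57 for saturated against monounsaturated, 89 for PA against PMA, 3 for SA against OA, 12 for PA against SA, 4 for PMA against OA and 102 for the mean. Cyclic loess gave 86 for SA, 284 for OA, 114 for PA against PMA, 43 for PA against SA, 20 for PMA against OA and 133 for the mean, and 257 for PA with PA replicate 1 left out. A trended robust spread gave 2 for PA, 213 for PMA, 98 for SA, 337 for OA, 196 for saturated against monounsaturated, 489 for PA against PMA, 63 for PA against SA, 30 for PMA against OA and 176 for the mean. The replicate block gave 1 for PA, 16 for PMA, 72 for OA, 5 for PMA against OA and 18 for the mean; 36 pairs of arrays of the same number in different groups correlated at a median of 0.006, from -0.433 to 0.396, so the numbers were not taken as pairs. Only the groups compared in the fit gave 21 for PMA, 102 for OA and 4 for PMA against OA, with fewer arrays. This fit gave 22 for PA against PMA and 2 for PA against SA, where the wider PA spread also weighs more. Array weights gave 1 for PA, 315 for PMA, 228 for SA, 1188 for OA, 255 for saturated against monounsaturated, 24 for SA against OA, 79 for PMA against OA and 506 for the mean. Without PA replicates 2 and 4 they were 1 for PA, 127 for PMA, 64 for SA, 264 for OA, 54 for PA against PMA, 2 for PA against SA and 18 for PMA against OA. Without PMA replicates 1 and 4 they were 3 for PMA, 51 for saturated against monounsaturated, 30 for PA against PMA, 2 for PMA against OA and 22 for the mean. With the controls split the correlations of the responses were 0.148 for PA and PMA, 0.104 for PA and SA, 0.217 for PMA and SA, 0.266 for PMA and OA and 0.368 for SA and OA, and that of PA and OA reversed to -0.0215, since the shared controls then no longer enter both. Cyclic loess gave 0.211 for PA and OA, and leaving out the dimmest genes 0.770 for SA and OA. Reversed in direction were the macrophage list in saturated against monounsaturated acids without the dimmest genes (adjusted p = 0.0485), the mitosis list in PA against PMA without PA replicates 2 and 4 (0.963) and the p53 list in PA against SA without PA replicates 2 and 4 (0.0431). Where no cause is given above, the cause was not tested. The number of arrays limits the precision, and what signal over background limits was not measured, since no background values were used here.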

Other observations

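The tests of the ERK genes in this part were chosen only after the results for Egr1 and Dusp6 were seen, although the genes and the bounds were written down before their values were looked at.

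Egr1 and Dusp6, which signalling through the kinase ERK induces, were higher with PA than with the mean of PMA, SA and OA, by 0.69 and 0.36. With PMA the Dusp6 arrays lay at 8.08 to 8.18, within those of the controls (8.07 to 8.33). With SA (7.84 to 8.05) and OA (7.88 to 7.93) they lay below the controls, and with PA at 8.21 to 8.44. As a hypothesis, lower ERK pathway output with the 3 other acids than with PA could set Egr1 and Dusp6 apart. In that case 9 other genes of ERK output (Phlda1, Spry2, Spry4, Dusp4, Ccnd1, Epha2, Epha4, Etv4 and Etv5) were to be higher with PA. Etv4 was higher past the threshold (0.16, adjusted p = 0.0479 with limma) and the other 8 did not pass. As a group they did not pass (camera of limma, p of 0.656, a single list and so not adjusted). The bound written against the hypothesis, a median at or below 0, was met by less than the members' spread (median -0.0003, SE of the mean 0.0244). The rule that it be met by more than that spread was applied after the value was seen, so these genes do not decide.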
